A study of Mus musculus with 5 samples.

How the data were processed

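The series measured messenger RNA of sorted regulatory T cells by RNA sequencing, in mice aged 13 days of the Foxp3-DTR/GFP line, in 3 libraries from skin-draining lymph nodes and 2 from skin. Per the labels' protocols, sorted cells were pelleted and frozen, a sequencing company purified RNA on columns, and cDNA was made with the SMARTer ultra-low-input kit, which amplifies small amounts of RNA by PCR. The sort markers, the number of cells, the tissue digestion and the number of animals behind each library are not given in the sources used here, so p-values measure the spread between these libraries, which may be technical in part.

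Per the submitters' processing notes, the authors used CASAVA 1.8.2, TopHat2 2.0.12 with Bowtie2 2.1.0.0, SAMtools 0.1.19.0 and HTSeq 0.6.1 on the mouse genome build mm10; the options and the strand setting are not given in the sources used here. The deposited table holds whole-number counts per gene symbol, with no normalization, in 1 column per library. Its header names 5 libraries and no gene column and was read as shifted by 1 cell. Of its 24089 lines, 5 are HTSeq summary rows, which were left out of library sizes and tests. Counts of reads that did not align uniquely made up 64.5 to 72.0% of all counts in the table, counts outside annotated genes 8.35 to 14.0% and genes 19.3 to 21.7%. Reads shared between near-identical copies were thus not assigned to genes, so genes with processed pseudogenes or close paralogs (Gapdh, at 3.59 CPM in lymph node Tregs, ribosomal protein genes, Hspa1a and Hspa1b, the Gimap, Ifit, Cd209, H2 and Phf11 families) are undercounted to an unknown degree. Reads of overlapping or antisense neighbors cannot be told apart where the strand was not used. No mitochondrially encoded gene is in the table.

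The 24084 genes included 9835 without a count. Gene counts per library ranged from 10468795 to 14595018. A count of 0 over a group allows up to 3 counts, that is 0.0719 CPM over the 3 lymph node libraries and 0.145 CPM over the 2 skin libraries; folds against an all-zero group are given against this floor as lower bounds, and ratios resting on 1 to 3 counts have an exact 95% interval for 2 Poisson rates. Intervals and floors cover counting error only, since PCR copies without molecular identifiers are not independent molecules. They do not cover transcripts lost before sequencing, so a bound holds for the counts and not for the cells.

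Counts were analyzed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with default settings (minimum count 10), which left 11437, library sizes were scaled by TMM, and skin was compared with lymph node by the quasi-likelihood F test with Benjamini-Hochberg adjustment over all tested genes, with an adjusted p under 0.05 as the threshold. The common dispersion was 0.843. The SE of a log2 fold change was taken as its size divided by the square root of F. CPM use TMM-scaled library sizes, except that the summed shares of marker lists are per unscaled gene counts. An exact permutation test of 2 against 3 libraries cannot go below a two-sided p of 0.1, so none is given and significance rests on spread shared across genes.

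Before the data were examined, 38 gene lists were fixed from textbook knowledge, in 3 classes (biology, technical and markers of other cell types), of which 29 had 5 or more tested members. They were tested two-sided with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists, and again with the correlation estimated from the data; 13 lists were called with the preset value (10 up and 3 down) and 0 with the estimated one (8 at an unadjusted p under 0.05). Setting members without a count in 1 group at their bound left the medians of the 13 called lists as they were. The rule for named genes was also fixed then. It takes the 12 largest rises and 12 largest falls among called genes with an average log2 CPM of 5 or more and no overlap between groups, leaving out predicted genes, mitochondrial genes and antigen receptor segments. It adds up to 4 members of each list by adjusted p, or the 2 most abundant where none passed, every chemokine receptor past the threshold, and Foxp3, Il2ra, Ctla4, Ccr6, Ccr7, Il1rl1, Gata3, Klrg1, Areg and Il7r. Some genes that the rule takes are not reported here. Ikzf2, Nrp1, Izumo1r, Tnfrsf1b, Havcr2, Fgl2, Pdcd1, Tcf7, Id3, S1pr1, Ccr8, Ccr4, Rgs1, Egr1, Zfp36, Hspa1a, H2-Aa, H2-Ab1, Hmgcs1, Lrrc32, Mcl1, Xcr1, Ccr1 and Gapdh fall outside it and were chosen after their values were seen. Gene positions come from GENCODE M21, whose assembly GRCm38 is mm10, matched by symbol.

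The fitting functions were tested on counts simulated for this comparison from the real gene means and library sizes, in 5 tables of about 11072 genes with 200 changed genes each. With the dispersions of these libraries, 0, 2.00, 12.4 and 22.0% of genes changed by 2, 4, 8 and 16-fold were recovered, and 3 of 94 calls were false. With a dispersion of 0.05 (about 11307 genes) the shares were 40.0, 99.2, 100.0 and 100.0%, and 38 of 886 calls were false. A list of 20 genes of which all were raised 4-fold was called by camera in 5 of 5 tables with the preset correlation and in 0 of 5 with the estimated one at the dispersions of these libraries, and 0 of 100 unchanged lists were called. Genes were drawn independently and with the same dispersion in both groups. These tables thus cannot show whether the preset correlation is too low for lists whose members vary together. Nor can they give the share of false calls where the spread differs between groups. The real skin libraries differed more than 4-fold in 38.0% of genes, against 7.78 to 8.03% for pairs of lymph node libraries. Estimated correlations of the real lists ranged from -0.0755 (innate lymphoid) to 0.389 (B and plasma cell).

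Alternatives fixed before the data were examined were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter (5 CPM in 2 libraries), the replicate number as a block, each library left out in turn, a 2-fold threshold, library sizes without ribosomal and the 20 most abundant genes, and for lists fry and a prior count of 0.5. Without 1 skin library, the other stands alone and is assumed to vary like the lymph node libraries. Added after the data were seen were a minimum average log2 CPM of 5, thinning of all libraries to equal depth, and the removal of GC content and length trends through splines (11364 of 11437 tested genes had both values). The trends were first removed with uncentered offsets, which also replaced the TMM scaling, and then with offsets centered at a median of 0 in each library; both are given.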

Results

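Regulatory T cells (Tregs), the Foxp3-expressing CD4 T cells that restrain immune responses, were profiled by RNA sequencing in mice aged 13 days. In this line (Foxp3-DTR/GFP) the Foxp3 locus also drives a diphtheria toxin receptor and green fluorescent protein. Sorted Tregs came from the lymph nodes that drain the skin (3 libraries) and from the skin itself (2 libraries). Counts assigned to genes numbered 14263710, 12305644 and 14595018 in the lymph node libraries and 10787378 and 10468795 in the skin libraries. At least 1 count was found for 12173, 12540 and 12338 genes in the lymph node libraries, but for 9894 and 9192 genes in the skin libraries. The comparison asks how Tregs of neonatal skin differ in expression from those of the draining nodes. Values below are CPM (counts scaled to a common library size) as mean ± SD over n = 3 lymph node and n = 2 skin libraries, in that order, and fold changes are skin relative to lymph node.

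Both sources expressed the genes that define Tregs. Foxp3 (chromosome X, 7573644 to 7595245, mm10), the lineage transcription factor, was at 94.8 ± 5.09 CPM in lymph node and 97.8 ± 28.1 CPM in skin Tregs (log2 fold change 0.05, SE 0.36, adjusted p = 0.954). Il2ra, the high-affinity interleukin-2 receptor chain, was at 1303 ± 136 CPM and 1204 ± 139 CPM (log2 fold change -0.11, SE 0.18, adjusted p = 0.744). Neither difference exceeded the spread between libraries. Within the list of Treg identity genes, 4 of the 18 tested members were higher, 3 lower and 11 not past the threshold by edgeR's quasi-likelihood test; adjusted over the list alone, 4 were higher and 4 lower. Ctla4, an inhibitory receptor by which Tregs strip co-stimulatory ligands, rose from 715 ± 94.3 CPM to 2389.9 ± 272 CPM (log2 fold change 1.74, SE 0.19, adjusted p = 0.0271). Tigit, a second inhibitory receptor, rose from 269 ± 28.6 CPM to 1234 ± 101 CPM (log2 fold change 2.20, SE 0.19, adjusted p = 0.0224). Capg and the transcription factor gene Ikzf2 (Helios) rose by log2 fold changes of 1.72 and 0.89 (adjusted p = 0.0260 and 0.0484). Gpr83, a G protein-coupled receptor abundant in lymphoid Tregs, had 668 ± 158 CPM in lymph node Tregs and 1 count over both skin libraries, a lymph node to skin ratio of 13889 (95% counting interval 2493 to 548589), with an adjusted p of 0.0124. Nrp1 (neuropilin 1) fell from 515 ± 77.9 CPM to 72.5 ± 25.2 CPM and Izumo1r (folate receptor 4) from 1286 ± 209 CPM to 4.65 ± 5.87 CPM (adjusted p = 0.0327 and 0.0452). The list as a whole was not called (camera adjusted p = 0.609, direction up, against a median log2 fold change of -0.11).

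Skin Tregs differed from lymph node Tregs in genes of activation, homing, naive T cell state and other cell types, described by group below. Of 11437 genes tested, 881 passed an adjusted p of 0.05 in edgeR, 275 higher and 606 lower in skin. The 606 lower genes included 369 with no count in either skin library, and 28 of the higher genes had no count in any lymph node library. A group without counts shows no spread of its own. The p-values of these genes thus rest on the spread in the other group and on spread shared across genes. Among genes with an average log2 CPM of 5 or more, the calls split the other way, into 239 higher and 156 lower. All skin values lay above all lymph node values for 1916 genes (16.8% of those tested) and below them for 3833 (33.5%), where chance gives 10% in each direction. The smallest adjusted p was 0.0124 and the median among the calls 0.0460. All 881 called genes kept their sign when any 1 lymph node library was left out. This was close to fixed in advance, since 0 of them had overlapping values between the groups. In those fits edgeR called 0 genes (2361 to 2485 at an unadjusted p under 0.05). Without skin library 1 it called 6065 and without skin library 2 4904. With all 5 libraries, DESeq2 called 3351, limma-voom 2231 and edgeR without a low-count filter 315, and uncentered GC and length offsets turned the split to 1954 higher and 888 lower.

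In the skin libraries the summed CPM of myeloid markers was 9.55-fold higher (median log2 fold change 5.91 over the 17 tested members) and fewer genes were detected. Among called genes with an average log2 CPM of 5 or more, the 12 with the largest rise in skin were Cd36, Ednrb, Pf4, Cd209a, Clec10a, Cd209d, Cbr2, Sirpa, Cd163, Krt14, Wfdc17 and Mrc1, and 11 of them had no count in any lymph node library. Mrc1, the macrophage mannose receptor, had 249.6 ± 158 CPM in skin and 1 count over the 3 lymph node libraries, a ratio of 10562 (95% counting interval 1895 to 417238). Cd36, a scavenger receptor for lipids, had 192 ± 42.5 CPM in skin, at least 2679-fold higher than the lymph node floor, and Krt14, a keratin of basal keratinocytes, had 89.2 ± 28.8 CPM, at least 1231-fold higher. The bounds of the 11 genes ranged from 1179.5-fold to 2679-fold, with adjusted p from 0.0275 to 0.0489. These bounds pool 2 skin libraries that differed widely for some genes (Cd163 at 25.5 and 157 CPM) and little for others (Ednrb at 196 and 181 CPM). The 12 with the largest fall were Gimap7, Ssbp2, Satb1, Cd160, Gata1, Gpr83, Kbtbd4, Gabrr2, Alg3, Phf11c, Ppan and Dph7. Again 11 had no count in either skin library, with bounds from at least 531-fold lower (Dph7) to at least 1388-fold lower (Gimap7). These bounds do not cover loss of transcripts before sequencing. Of 6660 genes at 20 CPM or more in lymph node Tregs, 586 lay under 1 CPM in skin library 1, 1069 in skin library 2 and 282 in both. Gimap7, a GTPase of the immunity-associated family, was at 199 ± 66.5 CPM in lymph node Tregs (adjusted p = 0.0224), and Satb1, a chromatin organizer of T cells, at 149 ± 15.3 CPM (adjusted p = 0.0209).

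**Figure D1:**
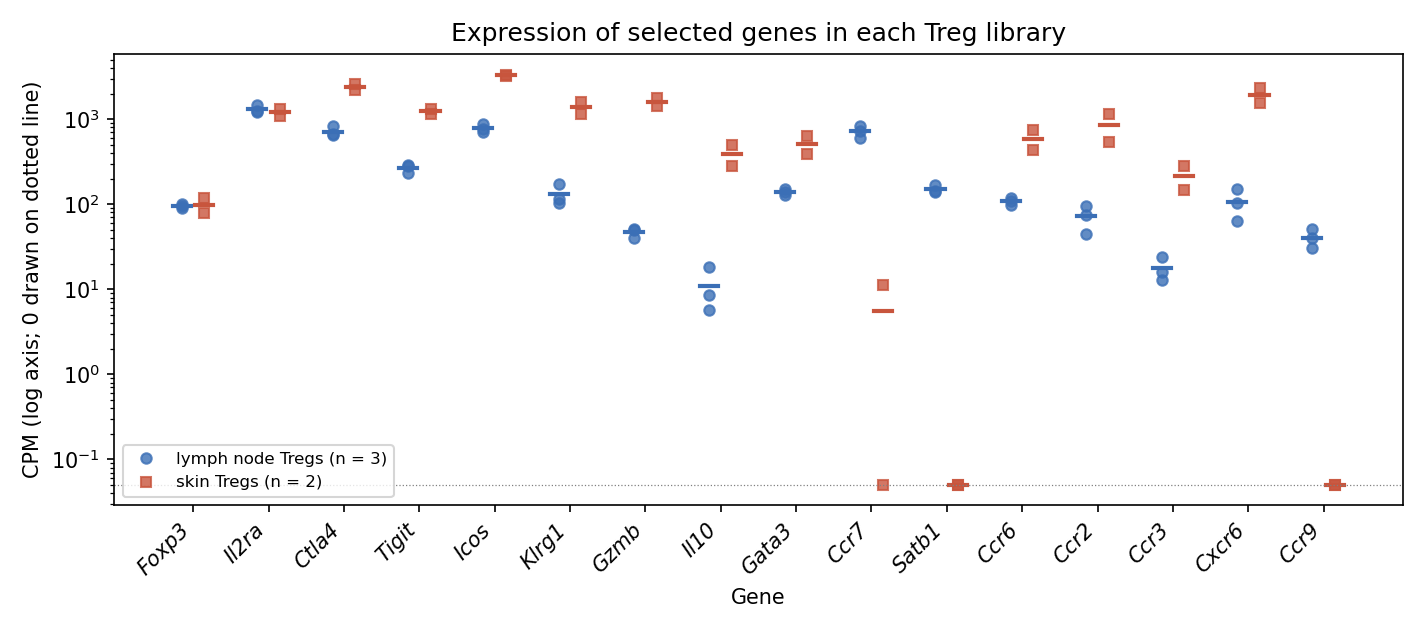
CPM (log axis) of 16 genes in each library, with lymph node Tregs as blue circles (n = 3) and skin Tregs as red squares (n = 2). Short bars are group means and values of 0 sit on the dotted line. Foxp3 and Il2ra overlap between the groups, Ctla4 to Gata3 lie higher in both skin libraries, Ccr7, Satb1 and Ccr9 lie lower, and Ccr6, Ccr2, Ccr3 and Cxcr6 lie higher.

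Genes of activated, effector Tregs were higher in skin as a group. In this list 10 of the 20 tested members were higher, 0 lower and 10 not past the threshold; adjusted over the list alone, 13 were higher and 0 lower (camera adjusted p = 3.01e-09, and 0.0829 as an adjusted p with an estimated correlation). Gzmb, which encodes the cytotoxic protease granzyme B, rose from 47.2 ± 6.05 CPM to 1597 ± 235 CPM (log2 fold change 5.08, SE 0.23, adjusted p = 0.0124). Icos, a co-stimulatory receptor, rose from 781 ± 81.2 CPM to 3307 ± 67.4 CPM (log2 fold change 2.08, SE 0.16, adjusted p = 0.0209). Cd44, an adhesion receptor of antigen-experienced T cells, rose from 275 ± 26.4 CPM to 1828 ± 141 CPM (log2 fold change 2.73, SE 0.18, adjusted p = 0.0169). Klrg1, a marker of terminally differentiated Tregs, rose from 131 ± 38.8 CPM to 1375 ± 295 CPM (log2 fold change 3.40, SE 0.32, adjusted p = 0.0224). Il10, an anti-inflammatory cytokine gene, rose from 10.9 ± 6.62 CPM to 390.0 ± 150.1 CPM (log2 fold change 5.16, adjusted p = 0.0340). Tnfrsf9 (4-1BB) and Tnfrsf1b, a tumor necrosis factor receptor, rose by log2 fold changes of 1.72 and 1.30 (adjusted p = 0.0265 and 0.0434). Havcr2, Fgl2 and Maf rose as well. Macrophages also express these genes and Il10, and myeloid markers were 9.55-fold higher in sum in the skin libraries. Pdcd1 (PD-1) was at 296 ± 39.0 CPM and 260.1 ± 81.3 CPM, within the spread (adjusted p = 0.738).

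The list of tissue Treg genes moved in the same direction. All 18 tested members had a positive fold change, 6 past the threshold and 9 when adjusted over the list alone (camera adjusted p = 1.28e-08, and 0.0775 as an adjusted p with an estimated correlation). Myeloid markers were 9.55-fold higher in sum in the same skin libraries, and the list of group 2 and 3 innate lymphoid cells, which shares Gata3, was just past the threshold (camera adjusted p = 0.0499, and 0.282 as an adjusted p with an estimated correlation), a call lost in 8 of the 11 alternatives for the list tests. Gata3, a transcription factor of type 2 responses, rose from 139.9 ± 10.5 CPM to 508 ± 174 CPM (log2 fold change 1.86, SE 0.28, adjusted p = 0.0421). Rora, which encodes a nuclear receptor, rose from 56.3 ± 25.2 CPM to 468 ± 98.5 CPM, and Id2, a helix-loop-helix inhibitor, from 75.0 ± 32.5 CPM to 758 ± 228 CPM (adjusted p = 0.0434 and 0.0381). Areg, which encodes the repair factor amphiregulin, had 1 count in lymph node Tregs against 7.82 ± 2.44 CPM in skin, a ratio of 328 (95% counting interval 58.1 to 13053) with an adjusted p of 0.0488. Il1rl1, the interleukin-33 receptor, had 24.4 ± 9.10 CPM in lymph node Tregs, but 199 CPM in skin library 1 and 28.2 CPM in skin library 2 (adjusted p = 0.177). Among T helper regulators only Gata3, Rora and Maf of 16 passed the threshold, all higher, and the list was not called (3 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.219, direction up, against a median of -0.05).

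Genes of naive and central lymphoid T cells were lower in skin as a group, in libraries that also held fewer detected genes. Here 0 of the 20 tested members were higher, 8 lower and 12 not past the threshold; adjusted over the list alone, 0 were higher and 11 lower (median log2 fold change -3.15; camera adjusted p = 0.000152, and 0.145 as an adjusted p with an estimated correlation). Bcl2, an anti-apoptotic gene, fell from 717 ± 179 CPM to 22.2 ± 9.98 CPM (log2 fold change -5.01, SE 0.47, adjusted p = 0.0229). Lef1, a transcription factor of resting T cells, fell from 532 ± 42.2 CPM to 71.5 ± 12.8 CPM (log2 fold change -2.90, SE 0.25, adjusted p = 0.0224). Tcf7 and Id3, transcriptional regulators, fell by 6.83 and 5.58 on the log2 scale (adjusted p = 0.0305 and 0.0302). S1pr1, the receptor for egress from lymph nodes, fell from 1142 ± 99.1 CPM to 143 ± 60.8 CPM (adjusted p = 0.0302). Ccr7, the receptor for lymph node chemokines, had 721 ± 114 CPM in lymph node Tregs against 11.2 CPM and 0 in the skin libraries, but with an adjusted p of 0.0679 it did not pass. Il7r was at 241 ± 65.1 CPM and 434 ± 144 CPM (adjusted p = 0.179).

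Among chemokine receptor genes, Cxcr6, Ccr6, Ccr2 and Ccr3 were higher and Ccr9 lower in skin. Of 18 tested receptors, 13 did not pass the threshold; adjusted over the list alone, 7 were higher and 3 lower (camera adjusted p = 0.00779, and 0.172 as an adjusted p with an estimated correlation). Cxcr6 (chromosome 9, 123806475 to 123811760), a receptor of tissue-resident T cells, rose from 105 ± 43.7 CPM to 1928 ± 546 CPM (log2 fold change 4.19, SE 0.43, adjusted p = 0.0253). Ccr6 (chromosome 17, 8236043 to 8257141), the receptor for CCL20, rose from 109 ± 10.2 CPM to 587 ± 221 CPM (log2 fold change 2.43, SE 0.30, adjusted p = 0.0342). Ccr2 (chromosome 9, 124101950 to 124113557) rose from 72.0 ± 25.8 CPM to 849 ± 431 CPM (log2 fold change 3.56, SE 0.48, adjusted p = 0.0381). Ccr3 (chromosome 9, 124021972 to 124031689) rose from 17.7 ± 5.74 CPM to 214 ± 97.1 CPM (log2 fold change 3.60, SE 0.50, adjusted p = 0.0402). Ccr9 (chromosome 9, 123678439 to 123784330), a gut-homing receptor, had 40.5 ± 10.5 CPM in lymph node Tregs and no count in skin, at least 280.4-fold lower (adjusted p = 0.0411). Ccr8 was at 214 ± 14.1 CPM and 566 ± 236 CPM (adjusted p = 0.0523), and Ccr4, a receptor linked to skin homing, at 60.5 ± 15.4 CPM and 61.0 ± 70.6 CPM (adjusted p = 0.994). Myeloid cells also express Ccr2, and myeloid markers were higher in the same skin libraries. Whether Ccr2 and Ccr3 signal comes from myeloid cells cannot be told apart from Treg expression. The receptor list was not called without skin library 2 (camera adjusted p = 0.105) or by fry (0.0565). Of 7 chemokine ligand genes tested only Ccl6 passed, with no count in lymph node and 39.1 ± 7.19 CPM in the skin libraries, at least 541-fold higher (adjusted p = 0.0463; 1 higher and 2 lower adjusted over the list alone; list camera adjusted p = 0.968). Myeloid markers were 9.55-fold higher in sum in these skin libraries, and the source of Ccl6 was not tested.

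In the list of skin homing and retention genes 4 of the 18 tested members were higher, 2 lower and 12 not past the threshold; adjusted over the list alone, 6 were higher and 2 lower (camera adjusted p = 0.0155, and 0.194 as an adjusted p with an estimated correlation). Fut7 and Gcnt1, which encode enzymes that build selectin ligands, rose from 8.51 ± 2.71 CPM to 105 ± 16.4 CPM and from 15.5 ± 3.35 CPM to 295 ± 121 CPM (adjusted p = 0.0452 and 0.0253). Itgae (CD103), an integrin that binds epithelial E-cadherin, rose from 100.5 ± 34.4 CPM to 1028 ± 101 CPM (log2 fold change 3.36, SE 0.36, adjusted p = 0.0271). Itgav, another integrin gene, rose by a log2 fold change of 2.40 (adjusted p = 0.0452). Itga4 and Rgs1 fell by 1.91 and 1.46 on the log2 scale (adjusted p = 0.0440 and 0.0494). The list call was lost without skin library 1 (camera adjusted p = 0.134), without skin library 2 (0.0921) and with the stricter filter (0.0539). Myeloid markers were 9.55-fold higher in sum in the same skin libraries.

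Proliferation and glycolysis genes were higher in skin as groups, in libraries where myeloid markers were 9.55-fold higher in sum. In the cell cycle list 3 of the 35 tested members were higher, 0 lower and 32 not past the threshold; adjusted over the list alone, 8 were higher and 1 lower. A positive fold change was found for 30 members (camera adjusted p = 2.49e-06, and 0.0775 as an adjusted p with an estimated correlation). Mki67, which encodes the proliferation antigen Ki-67, rose from 99.6 ± 20.4 CPM to 764 ± 199 CPM (log2 fold change 2.94, SE 0.29, adjusted p = 0.0253). Mcm6 and Rrm2, genes of DNA replication and nucleotide synthesis, rose by log2 fold changes of 2.30 and 1.82 (adjusted p = 0.0381 and 0.0452). For glycolysis and hypoxia genes 4 of the 21 tested members were higher, 0 lower and 17 not past the threshold; adjusted over the list alone, 6 were higher and 0 lower (camera adjusted p = 7.55e-06, and 0.0775 as an adjusted p with an estimated correlation). Aldoa (aldolase A) rose from 803 ± 90.8 CPM to 3589.9 ± 161 CPM (log2 fold change 2.16, SE 0.17, adjusted p = 0.0209). Tpi1, Pkm and Hif1a, which encodes an oxygen-sensing factor, rose by 2.15, 1.58 and 2.18 on the log2 scale (adjusted p = 0.0381, 0.0452 and 0.0463). Genes of oxidative phosphorylation were not called as a list (0 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.627, direction up, against a median of -0.18). Only Uqcrc2 of 23 tested passed, falling from 522 ± 19.6 CPM to 197 ± 13.9 CPM (adjusted p = 0.0406).

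Immediate early and dissociation-sensitive genes were higher in the skin libraries as a group, in which myeloid markers were 9.55-fold higher in sum. In this technical list 6 of the 27 tested members were higher, 1 lower and 20 not past the threshold; adjusted over the list alone, 12 were higher and 1 lower (camera adjusted p = 4.83e-06, and 0.0775 as an adjusted p with an estimated correlation). Fos rose to 564 ± 90.0 CPM (log2 fold change 5.33, SE 0.62, adjusted p = 0.0308), and Dusp1 rose from 9.01 ± 1.24 CPM to 255 ± 152 CPM (log2 fold change 4.82, SE 0.52, adjusted p = 0.0271). Nr4a1, a gene induced by T cell receptor signals, rose from 162 ± 32.5 CPM to 806 ± 133 CPM (log2 fold change 2.32, SE 0.26, adjusted p = 0.0299). Egr1, an immediate early gene as well, fell from 97.0 ± 21.3 CPM to 6.10 ± 0.416 CPM (adjusted p = 0.0405). Klf6 rose by a log2 fold change of 2.15, and Zfp36 and Hspa1a, which shares reads with its copy Hspa1b, passed too. Among NF-kB targets Tnfaip3, Nfkb1 and Gadd45b rose (3 of 20 tested; 4 higher and 1 lower adjusted over the list alone), with log2 fold changes of 3.01, 1.65 and 3.33. The list was not called (camera adjusted p = 0.0822).

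Interferon response and ribosomal protein genes were lower in skin as groups. The skin libraries also held fewer detected genes (9894 and 9192, against 12173 to 12540) and differed more than 4-fold from each other in 38.0% of genes. In the interferon list 0 of the 23 tested members were higher, 2 lower and 21 not past the threshold; adjusted over the list alone, 0 were higher and 7 lower (camera adjusted p = 0.00779, and 0.488 as an adjusted p with an estimated correlation). Irf9, a subunit of the interferon-activated transcription factor, fell from 354 ± 41.8 CPM to 39.1 ± 7.43 CPM (log2 fold change -3.18, SE 0.30, adjusted p = 0.0224). Ifit1 had 189 ± 148 CPM in lymph node Tregs and 3 counts over both skin libraries, a lymph node to skin ratio of 1349.9 (95% counting interval 462 to 6547) with an adjusted p of 0.0424. The list was not called without skin library 2 (camera adjusted p = 0.0921). Of 76 ribosomal protein genes 69 had a negative fold change, 4 of them past the threshold (among them Rpl8, Rps15 and Rps19) and 0 when adjusted over the list alone, and 56 lay below every lymph node library in both skin libraries. The median log2 fold change was -1.42 (camera adjusted p = 0.000152, and 0.559 as an adjusted p with an estimated correlation). Together they took 2.51, 1.62 and 1.93% of gene counts in lymph node and 0.771 and 0.928% in skin Tregs. Many of these genes have near-identical processed copies, so their levels in counts of uniquely aligned reads are uncertain.

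The T cell receptor and co-stimulation list was not called (camera adjusted p = 0.394, with 0 higher and 5 lower adjusted over the list alone). In both skin libraries 15 of 20 members lay below every lymph node library. The skin libraries held fewer detected genes, and myeloid markers were 9.55-fold higher in sum in them. Cd5, a negative regulator of receptor signaling, fell from 1035 ± 74.9 CPM to 415 ± 17.5 CPM (log2 fold change -1.32, SE 0.18, adjusted p = 0.0381). The kinase gene Lck fell from 2912 ± 174 CPM to 1588 ± 249.9 CPM (log2 fold change -0.87, SE 0.18, adjusted p = 0.0492). Lck did not pass with RLE factors (adjusted p = 0.0534), and Cd5 and Lck were at 0.056 and 0.24 under uncentered GC and length offsets, which moved the median of all genes from -0.21 to 0.98. Among T cell cytokines Il10 and Areg were higher and Lta (lymphotoxin alpha) lower, from 293 ± 12.7 CPM to 52.8 ± 14.7 CPM (log2 fold change -2.47, SE 0.31, adjusted p = 0.0352), of 10 tested (3 higher and 3 lower adjusted over the list alone; list camera adjusted p = 0.585, direction up, against a median of -0.40). Of 23 cytokine receptor genes only Il18rap, a chain of the interleukin-18 receptor, passed, rising from 13.1 ± 2.77 CPM to 187 ± 117 CPM (adjusted p = 0.0411; 1 higher and 0 lower adjusted over the list alone; list camera adjusted p = 0.0822).

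Markers of other cell types differed between the libraries. Myeloid and Langerhans cell markers together took 9273 and 11256 CPM in the skin libraries against 767 to 1356 in lymph node libraries. Of the list, 9 of the 17 tested members were higher, 0 lower and 8 not past the threshold, and 15 were higher when adjusted over the list alone (camera adjusted p = 2.91e-11, and 0.0775 as an adjusted p with an estimated correlation). The most abundant were Cd74 (309 ± 182 CPM and 4680.1 ± 1426 CPM), H2-Aa (30.1 ± 33.7 CPM and 1224 ± 5.40 CPM) and H2-Ab1, all of antigen presentation by major histocompatibility class II. Lyz2 (lysozyme) rose from 8.61 ± 3.23 CPM to 412 ± 49.5 CPM (log2 fold change 5.58, SE 0.46, adjusted p = 0.0221). Keratinocyte markers took 266 and 372 CPM in skin and 23.9 to 38.1 in lymph node libraries (1 of 10 tested members higher, Krt14; 4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0111, and 0.318 as an adjusted p with an estimated correlation). Without lymph node library 2 or skin library 2 the keratinocyte list was not called (camera adjusted p = 0.0750 and 0.0927). The list of group 2 and 3 innate lymphoid cells was just past the threshold (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0499, and 0.282 as an adjusted p with an estimated correlation). Its only called member was Gata3, also a tissue Treg gene, and the call was lost in 8 of the 11 alternatives for the list tests, among them without lymph node library 1 (0.123), skin library 1 (0.368) and skin library 2 (0.0703). B and plasma cell markers took 21.9 and 84.5 CPM in skin and 91.5 to 269.7 in lymph node libraries (0 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0941, and 0.0156 without lymph node library 2). CD8 T and NK cell markers took 1958 and 2590.1 in skin and 204 to 297 in lymph node libraries, where Gzmb, also of the effector Treg list, made up most of the skin counts (3 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.632, direction up, against a median of -1.86).

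**Figure D2:**
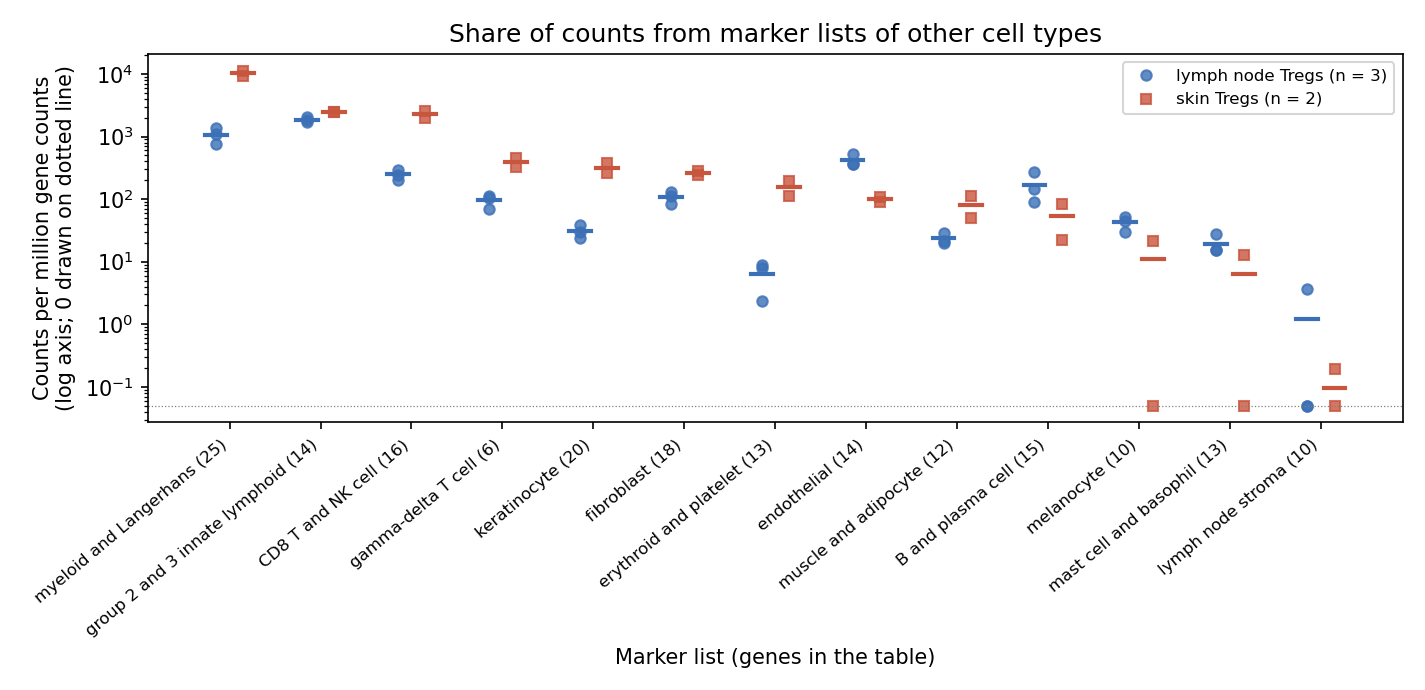
CPM of all gene counts (log axis) summed over each marker list of another cell type, per library, with lymph node Tregs as blue circles (n = 3), skin Tregs as red squares (n = 2) and group means as short bars. The number of genes stands in parentheses and values of 0 sit on the dotted line. Myeloid and Langerhans markers reach 9273 and 11256 CPM in the skin libraries against 767 to 1356 in the lymph node libraries, and endothelial, B cell, melanocyte and mast cell lists lie lower in both skin libraries.

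Lymph node libraries resembled one another more than the skin libraries did. Across 11437 genes, which are not independent replicates, Pearson correlations of log2 CPM were 0.902 to 0.910 among lymph node libraries, 0.612 between the skin libraries and 0.572 to 0.620 between the groups. The skin libraries differed more than 4-fold from each other in 38.0% of genes, against 7.78 to 8.03% for pairs of lymph node libraries. Skin library 1 correlated with each lymph node library (0.615 to 0.620) no less than with skin library 2 (0.612), so the skin libraries formed no group by this measure. The first principal component (59.1% of variance) separated the groups, with the skin libraries apart at 102 and 257. The second (33.4%) separated the skin libraries from each other.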

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

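The tests on myeloid markers, on the share of other cells and on tissue handling were chosen after the results were seen, as was the centered form of the GC and length correction; those on depth and random loss were set before. Counts outside annotated genes, which no comparison uses, took 13.2 ± 1.06% of all counts in the skin libraries (n = 2) and 10.3 ± 1.72% in the lymph node libraries (n = 3), a share above the limit that a count of 0 allows, and were not tested further.

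More genes were lower than higher in skin, with 9894 and 9192 genes detected against 12173 to 12540. Depth did not account for this, since lymph node libraries thinned to the shallowest skin library still held at least 12086 genes on average. Of 6660 genes at 20 CPM or more in lymph node Tregs, 282 lay under 1 CPM in both skin libraries. Independent loss at a rate set by lymph node level alone predicts 149.7, a ratio of 1.88 against 0.882 to 1.13 by chance. That argues against such loss as the whole cause, although 1091 others were absent from 1 skin library alone. Independent loss at rates that differ between genes in other ways would also raise the ratio, so it does not decide that case. With GC and length trends removed, lower calls were 2.30 times the higher ones, against 2.20 times before. The uncentered correction, which also moved the median of all genes, gave a ratio of 0.454. Fold changes hardly followed GC content across genes (Spearman correlation 0.0261). Whether GC content or length contributed cannot be decided this way, because offsets cannot raise a count of 0 or the number of genes detected. Of the 606 lower calls, 369 had no count in either skin library. A loss shared by both skin libraries, such as lower RNA input or quality, and a real difference between tissues were not tested and stay open as candidate explanations.

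Myeloid markers were higher in the skin libraries, among them Cd74 at 3672 and 5688 CPM and Lyz2 at 377 and 447 CPM. Of 17 such markers under 5 CPM in lymph node Tregs, 9 lay higher in both skin libraries than in every lymph node library and 5 were 0 throughout. That count restates the pattern on markers kept for a low lymph node value and decides nothing. Myeloid cells or their RNA in the skin sort cannot be told apart from expression by skin Tregs, because any source in skin shares the same 2 libraries. A lower share of Tregs that raises fibroblast and endothelial cells as much as myeloid cells is argued against. The ratio of the median of 29 fibroblast and endothelial markers to that of the myeloid markers was 0 in both skin libraries. Other lists went both ways, with keratinocyte markers at 10.5 and B and plasma cell markers at 0.316 times their lymph node share. A lower share of Tregs as such was not tested. T cell receptor and co-stimulation genes summed to 0.649 times their lymph node share, and Treg identity genes to 1.20 times. Whether Il10, Ccr2, Ccr3, Havcr2 and Maf signal comes from myeloid cells cannot be told apart from Treg expression either, since both would share these 2 libraries. The mean skin library 2 to skin library 1 log2 ratio of these 5 genes lay -0.525 SD from that of 15 myeloid markers, but with an SD of 1.496 among single markers this comparison decides nothing. Activated Tregs that take up or express such transcripts in skin remain open and untested.

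Immediate early genes were higher in skin, with 14 of 27 tested members above every lymph node library in both skin libraries and 6 below. Handling of skin before the sort may account for them, but it cannot be told apart from tissue activation, because tissue and handling go together in all 5 libraries. Egr1, also an immediate early gene, fell while Fos and Dusp1 rose.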

How the results depend on the processing

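The minimum of average log2 CPM, the thinning and both GC and length corrections were chosen after the data were seen. Against 881 calls (275 higher, 606 lower), DESeq2 gave 3351 (1213 and 2138), limma-voom 2231 (566 and 1665), no low-count filter 315 (136 and 179), genes with an average log2 CPM of 5 or more 395 (239 and 156) and uncentered GC and length offsets 2842 (1954 and 888). The average CPM limit leaves fewer genes to call, and the uncentered offsets moved the median log2 fold change of all genes to 0.98; for the others the cause was not tested. Upper-quartile factors moved that median from -0.21 to -0.37 with 876 calls, while RLE factors gave 912, the stricter filter 1261, library sizes without abundant genes 879, a 2-fold minimum 877, thinning 906 and centered offsets 968. DESeq2 also called all 881 genes and limma-voom 857 of them.

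With 1 library left out, edgeR calls ranged from 0 without any of the lymph node libraries to 6065 without skin library 1 (higher 0 to 2110, lower 0 to 3955), where skin library 2 stands alone. Chemokine receptor calls ranged from 0 to 15 and Treg identity calls from 0 to 11, and the number of called lists from 8 without skin library 2 to 13. Fewer lymph node libraries leave fewer degrees of freedom for the spread, and a lone skin library adds no spread of its own. All 90 called genes of the naming rule lost their call without any 1 lymph node library, and 0 did without a skin library. Tnnt3, not called with all libraries, turned to -8.65 without skin library 1 and was 1.16 without skin library 2. With all libraries, the replicate block ended 83 of these 90 calls, the no-filter fit 18, uncentered offsets 9, limma-voom 2 and RLE factors 1 (Lck).

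Of the chemokine receptors, 5 passed with all libraries, against 11 by DESeq2, 9 by limma-voom and 10 with uncentered offsets. Il2ra, Cd5 and Lck turned positive with those offsets, at 1.18, 0.056 and 0.24, Il2ra above and Cd5 and Lck below the shifted median; over the named genes, these 3 included, 9 calls ended and 6 were added.

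The replicate numbers that skin and lymph node libraries share do not establish pairing. Deviations from the group means of libraries with the same number correlated at -0.0252 and -0.0236 across genes, with only 2 pairs. With the number as a block, 1 degree of freedom was left and edgeR called 21 genes (11 higher, 10 lower; 772 at an unadjusted p under 0.05), 0 chemokine receptors and 2 Treg identity genes.

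Of 13 called lists, 0 passed with an estimated correlation (8 at an unadjusted p under 0.05, lowest adjusted p = 0.0775), and fry called 18. Fry, which does not set a list against other genes, turned Treg identity (0.00554), TGF-beta (0.0224) and apoptosis (0.0105) to down. A prior count of 0.5 changed no list call, and RLE factors ended that of the innate lymphoid list (0.0529). Myeloid markers took 10264 CPM in skin and 10353 without ribosomal genes. The correlation between the skin libraries was 0.205 over the 500 most variable genes, a choice that favors genes in which they differ. Depth limits what absence means, since 0 counts over a group still allow 0.145 CPM in skin.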

Other observations

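No test of an explanation is made in this part. Lipid genes went both ways in the skin libraries, in which myeloid markers were 9.55-fold higher in sum and fewer genes were detected (9894 and 9192, against 12173 to 12540). Plin2, a lipid droplet coat gene, rose from 33.5 ± 2.51 CPM to 280.4 ± 61.6 CPM (log2 fold change 3.07, SE 0.31, adjusted p = 0.0253, edgeR), as did Cd36. Cpt2, an enzyme of mitochondrial fatty acid oxidation, and Slc27a4, a fatty acid transporter, had no count in skin and were at least 202-fold and 72.1-fold lower (adjusted p = 0.0484 and 0.0476). The list was not called (2 of 17 tested members higher, 2 lower; adjusted over the list alone, 2 and 2; camera adjusted p = 0.188). Among cholesterol synthesis genes, Dhcr7 had 114 ± 20.1 CPM in lymph node Tregs and 2 skin counts, a lymph node to skin ratio of 1176 (325 to 9710.0, 95% counting interval), and Sqle 1 skin count, a ratio of 461 (82.6 to 18248, 95% counting interval). Mvk had none and was at least 97.1-fold lower (adjusted p = 0.0327, 0.0470 and 0.0464). That list was not called either (0 of 21 tested members higher, 3 lower; adjusted over the list alone, 0 and 3; camera adjusted p = 0.7999), and Hmgcs1, at 96.8 and 0.300 CPM in the skin libraries, differed widely between them.

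In the TGF-beta pathway Itgav, an integrin that activates the latent cytokine, was the only call (1 of 16 tested members higher, 0 lower; adjusted over the list alone, 4 and 2; camera adjusted p = 0.602, direction up, against a median of -0.23). Lrrc32, which anchors latent TGF-beta on Tregs, was at 262 ± 26.0 CPM in lymph node Tregs and 0.562 and 42.8 CPM in the skin libraries (adjusted p = 0.208). Dtx1, a Notch target, had no count in skin, where fewer genes were detected, and was at least 135-fold lower (adjusted p = 0.0456; list: 0 of 12 tested members higher, 1 lower; adjusted over the list alone, 0 and 1; camera adjusted p = 0.250). Bcl2 was the only called apoptosis regulator (0 of 19 tested members higher, 1 lower; adjusted over the list alone, 1 and 2; camera adjusted p = 0.627, direction up, against a median of -0.06), while Mcl1 was at 238 ± 37.2 CPM and 229 ± 57.8 CPM (adjusted p = 0.926).

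On chromosome 9 the receptor genes Ccr9, Cxcr6, Xcr1, Ccr1, Ccr3 and Ccr2 lie in this order between 123678439 and 124113557 (mm10). Ccr9, at 1 end, had no count in skin, while its neighbor Cxcr6 rose. Ccr1, a receptor of myeloid cells, had no lymph node count and 7.39 and 103 CPM in the skin libraries (adjusted p = 0.0598).

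Both Xist, expressed from the inactive X chromosome, and Ddx3y, a Y-linked gene, were detected in most libraries. Xist was at 296, 0 and 81.6 CPM in the lymph node libraries and 41.8 and 412 CPM in the skin libraries, and Ddx3y at 0.0702, 304 and 138 CPM in the lymph node libraries and 145 and 48.9 CPM in the skin libraries. Lymph node library 1 thus held almost only Xist and lymph node library 2 only Ddx3y. Lymph node library 3 and both skin libraries held both genes, which points to animals of both sexes in each. Sex composition therefore differed between libraries and was not modeled. The list of sex-linked genes was not called (0 of 5 tested members higher, 0 lower; adjusted over the list alone, 0 and 0; camera adjusted p = 0.465, direction up, against a median of -1.15).

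Lists with fewer than 5 tested genes had no list test. Fibroblast markers took 286 and 242 CPM in the skin libraries and 83.1 to 129 in the lymph node libraries, with Thy1, which T cells also express, at 99.0 ± 29.4 CPM and 221 ± 31.3 CPM, and Sparc at 1.14 ± 1.86 CPM and 84.6 and 8.09 CPM. Endothelial markers took 110.0 and 89.2 and 358 to 519.9, although Lyve1, also a gene of some macrophages, had no count in lymph node and 66.2 ± 34.2 CPM in skin, at least 909.5-fold higher (adjusted p = 0.0452). Only 1 of the 14 endothelial markers averaged 5 CPM or more in lymph node Tregs. Erythroid and platelet markers took 111 and 198 and 2.38 to 8.77, where Pf4, which was called, made up most of the skin counts. Gamma-delta T cell markers took 448 and 324 and 69.3 to 112. Maf, also of the effector Treg list, was the only one tested and made up all of the skin counts. Melanocyte markers took 21.8 and 0 and 29.8 to 52.6, and mast cell and basophil markers 12.7 and 0 and 15.5 to 27.4. Muscle and adipocyte markers took 114 and 49.6 and 20.1 to 29.2, and lymph node stroma markers 0 and 0.191 and 0 to 3.70.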
